A study of Nasonia vitripennis and Nasonia giraulti with 4 samples.

How the data were processed

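The series measured DNA methylation by whole-genome bisulfite sequencing, in which bisulfite turns unmethylated cytosine into uracil, read as T, while methylated cytosine is still read as C. Per the labels' protocols, genomic DNA came from whole bodies of pools of 50 adults 24 h after eclosion, from the AsymCX strain of the parasitoid wasp Nasonia vitripennis and the R16A strain of its sister species Nasonia giraulti, and 15 µg of DNA went into each library. The labels list 4 samples. They are 1 N. giraulti female sample, 1 N. giraulti male sample and 2 N. vitripennis male samples that are told apart only by the sequencing machine, a GAIIx or a HiSeq 2000.

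The authors deposited 1 table of counts per species, which gives for each listed CpG position, per the file headers, the count of T reads and the count of C reads in each sex. The values are whole-number read counts with no normalization. The N. vitripennis table holds a single pair of male columns, so these were used as 1 library, and whether they sum both male samples is not stated. A further 2 columns of per-sample counts match no sample of the series and were not used in any step. Per the submitters' processing notes, the programs CASAVA 1.7 and 1.8.2, FastQC, Trimmomatic and BWA were used. The role of each program, the genome build, the filters on reads and bases, the treatment of PCR duplicates and the rule by which a CpG was listed are not given in the sources used here. Positions are given on numbered scaffolds as the tables give them, and positions with the same scaffold and coordinate in both tables were taken as the same CpG.

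The methylation level of a CpG was its C reads divided by its C and T reads. The overall level of a library was the C reads summed over all listed CpGs, divided by the summed reads. A CpG entered every other step with at least 10 reads, and was called methylated at a level of 10% or more. Intervals for single libraries are 95% exact binomial (Clopper-Pearson) intervals. Reads are not shown to be independent molecules, so the intervals cover counting error only. A background level was estimated for each library from the reads at CpGs in 1 kb windows whose mean level was under 5% in the male library of the other species. This background includes unconverted cytosines, sequencing errors and any weak methylation.

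The comparisons were made in fixed 1 kb windows, because no annotation of the build of the tables was used. Each window needed at least 5 CpGs with at least 10 reads in both libraries. The level of a window was the mean level over those CpGs. Read counts of windows and libraries are sums over CpGs, so a read that spans several CpGs is counted at each of them. The tests and the upper limits for counts of 0 take these counts as independent. Where CpGs share reads, the p-values and limits can therefore be too small. The libraries were compared with a two-sided Cochran-Mantel-Haenszel test with the CpG as stratum, with Benjamini-Hochberg adjustment over all windows tested. A window was called different at an adjusted p under 0.05 and a difference of at least 10 percentage points. Standard errors (SE) of window differences are over the CpGs of a window. Single CpGs were compared between the N. giraulti sexes with a two-sided Fisher's exact test under the same adjustment and thresholds. N. giraulti female was compared with N. giraulti male, and N. vitripennis male with N. giraulti male, so that the N. giraulti male library serves in both comparisons. Ratios of the shares of CpGs missing from a list have 95% intervals from 1000 bootstrap draws of scaffolds. With 1 library per group, each test compares these libraries and not the sexes or the species, and no spread between replicates can be given.

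These tests, the thresholds, the rule for named regions and the first set of alternatives were fixed before the data were examined. The rule names the 8 windows with the largest difference in each direction among those called, the 5 windows with the highest level in each N. giraulti library among windows with at least 20 CpGs, and the 3 single CpGs with the largest difference in each direction. The parts of the rule that name genes, the gene lists fixed with it, methylation by genomic feature, and the sum of both strands of a CpG were not run, since no annotation of that build was used here and the columns used do not separate strands. The comparison of the GAIIx with the HiSeq 2000 sample was not run, since the male counts come as 1 pair of columns.

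The alternatives were coverage minimums of 5 and 20 reads, leaving out CpGs above the 99th percentile of coverage, other level thresholds, no minimum difference or 25 points, Fisher's exact test on summed reads, a sign-flip test of CpG differences (exact, or 10000 draws in windows with many CpGs), 500 bp windows, at least 10 CpGs per window, and binomial thinning of the deeper library. Scaling the test by the dispersion between CpGs, centring the differences, subtracting the background, weighting CpGs equally, using only CpGs covered in all 3 libraries and thinning every CpG to 10 reads were added after seeing the data.

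The tests were tested on simulated data with the real CpGs and read depths. For the N. giraulti sexes, the test over 175872 windows recovered 20.9% of windows given a true mean shift of 9.13 points, 92.5% of those given 17.3 points and 100% of those given 25.4 points. For the species, the test over 167992 windows recovered 22.4%, 91.0% and 98.5% at 9.15, 17.4 and 24.9 points. No unchanged window or CpG was called in either simulation. Apart from the shifts, both simulated libraries were drawn from the same level at each CpG. The draws held no dispersion beyond counting error and no gap in background. The real libraries have both, so the recovery rates and the lack of false calls hold for that simpler setting only. The test of 7400314 single CpGs recovered 0% of CpGs given 8.98 or 17.1 points and 1.26% of those given 24.8 points, with the adjustment over all CpGs tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0 were used.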

Results

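CpG methylation was measured in whole bodies of young adult Nasonia wasps. Nasonia giraulti was represented by 1 female and 1 male library and Nasonia vitripennis by 1 male library. In these wasps females are diploid and males develop from unfertilised eggs and are haploid, and the series addresses differences in methylation between the sexes. The sister species can be compared at the same sex. The N. giraulti table listed 9741959 CpGs and that of N. vitripennis listed 13450749, of which 9117293 were in both. The N. giraulti female library had 212714690 reads at CpGs (mean 21.8 per CpG), the N. giraulti male library 308473882 (mean 31.7) and the N. vitripennis male library 195248645 (mean 14.5). At least 10 reads covered 7569126 CpGs (77.7%) in the N. giraulti female, 8425664 (86.5%) in the N. giraulti male and 7235990 (53.8%) in the N. vitripennis male. The groups have no replicates, and all intervals cover counting error only.

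Methylation was sparse in all 3 libraries and was concentrated in a small set of strongly methylated CpGs. CpGs with a level of 50% or more made up 1.01% of covered CpGs in the N. giraulti female (76435 CpGs, 95% interval 1.003–1.017%), 0.902% in the N. giraulti male (76017 CpGs, 0.896–0.909%) and 1.16% in the N. vitripennis male (83930 CpGs, 1.15–1.17%). At the 7400314 CpGs covered in both N. giraulti libraries the order turned, with 0.9995% in the female and 1.020% in the male. Their median level was 84.4% in the N. giraulti female, 86.4% in the N. giraulti male and 84.4% in the N. vitripennis male. No methylated read was seen at 65.7%, 58.1% and 94.5% of covered CpGs in these libraries. Strongly methylated CpGs were covered by more reads than CpGs under 10%, with means of 40.04 against 26.9 reads in the N. giraulti female, 42.0 against 36.2 in the N. giraulti male and 31.2 against 22.8 in the N. vitripennis male.

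The overall level was 3.22% in the N. giraulti female (95% interval 3.214–3.219%), 2.67% in the N. giraulti male (2.668–2.672%) and 1.45% in the N. vitripennis male (1.445–1.449%). At the lower threshold of 10%, methylated CpGs made up 5.03% (5.01–5.05%), 2.95% (2.94–2.96%) and 1.75% (1.74–1.75%) of covered CpGs. The background measured in windows with little methylation was 1.995% in the N. giraulti female, 1.77% in the N. giraulti male and 0.298% in the N. vitripennis male, so that these figures hold different amounts of background. The genome to which the N. giraulti reads were aligned is not given in the sources used here, and the N. giraulti background can depend on it. With the background subtracted, the overall level was 1.25%, 0.915% and 1.15%, higher in the N. vitripennis male than in the N. giraulti male. The subtracted values still weight CpGs by each library's own reads. At the CpGs covered in both N. giraulti libraries the read-weighted level was 3.26% in the female and 2.75% in the male. With the female levels weighted by the male depths it was 2.85% in the female, so most of that gap depended on the weights. The order of the libraries at 10% was not that at 50%. With at least 20 reads per CpG the share at 10% was 4.41%, 2.36% and 2.51%. It was then higher in the N. vitripennis male than in the N. giraulti male.

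**Figure D1:**
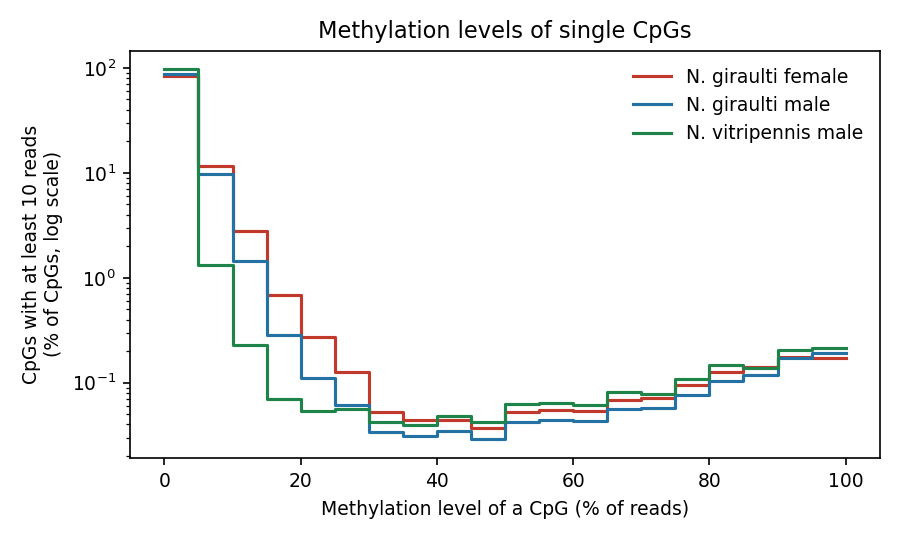
Share of covered CpGs (y axis, percent, log scale) by methylation level (x axis, percent of reads, steps of 5 points) in the N. giraulti female (red), N. giraulti male (blue) and N. vitripennis male (green) libraries, for CpGs with at least 10 reads. Most CpGs lie near 0 and a small group rises towards 100%, while the libraries differ mainly under 30%.

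Methylated CpGs lay next to each other. The shares here are over CpGs whose next covered CpG lay within 100 bp. Of CpGs at 50% or more, 58932 of 76435 in the N. giraulti female had such a neighbour. The counts were 58749 of 76017 in the N. giraulti male and 64001 of 83930 in the N. vitripennis male. That neighbour was also at 50% or more in 78.6% of cases in the N. giraulti female, 79.9% in the N. giraulti male and 78.1% in the N. vitripennis male. After a CpG under 50% the next CpG reached that level in 0.177%, 0.146% and 0.210% of cases. At the 10% threshold the next CpG was also methylated in 25.5%, 34.8% and 75.3% of cases, against 3.67%, 1.77% and 0.364% after a CpG under 10%. A uniform background at each library's depth would by itself put 2.39%, 1.15% and 0.279% of covered CpGs at 10% or more. The CpGs called methylated at 10% hold unlike amounts of background, so these shares do not compare the clustering of methylation between the libraries.

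The highest windows of both N. giraulti libraries were also highly methylated in N. vitripennis, whose levels here are over its own CpGs. On scaffold 3, positions 3230001 to 3231000, the mean level over 20 CpGs was 91.1% in the N. giraulti female and 93.2% in the male, the highest of both libraries among windows with at least 20 CpGs, and 82.3% in the N. vitripennis male. Scaffold 42 (336001 to 337000) had 89.1% and 90.5% in the N. giraulti female and male and 89.5% in N. vitripennis, and scaffold 11 (412001 to 413000) had 89.0%, 91.4% and 88.4%. The windows on scaffold 77 (388001 to 389000) and scaffold 18 (2727001 to 2728000) completed the list of the female library, at 90.8% and 89.4%. Those on scaffold 6 (1854001 to 1855000) and scaffold 18 (1316001 to 1317000) completed that of the male library, at 91.8% and 90.8%. In N. vitripennis these 4 windows were at 92.4%, 83.9%, 87.2% and 89.0%.

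The comparison of the N. giraulti sexes asked whether females and males methylate different parts of the genome. They shared almost all methylated windows. Of 175872 windows, 9675 had a mean level of at least 10% in both libraries, 229 in the female alone and 275 in the male alone. Of the 10179 windows methylated in either library, 97.7% differed by less than 10 points. No window was at 50% or more in 1 sex and under 5% in the other, among 3928 windows at 50% or more in either. The largest difference was 32.1 points.

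The test called 145 windows (0.0824% of those tested), of which 32 were higher and 113 lower in the female library. Without a minimum difference the direction turned, with 1241 windows higher and 753 lower in the female. Over the windows methylated in either library, the median difference, female minus male, was -0.884 points (SD over windows 3.67), the female was lower in 63.3% of them, and the median was negative on 74 of the 76 scaffolds with at least 20 such windows. With differences centred on the median at each level, which by construction balances the windows around 0, the split was 51 higher and 54 lower. In windows under 5% in both libraries the median level was 1.84% in the female and 1.71% in the male. Across all windows, which are not independent replicates, the levels had a Pearson correlation of 0.993 and a Spearman correlation of 0.291. Across the windows methylated in either library the correlations were 0.988 and 0.987.

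Among the windows called higher in the female, the largest difference was on scaffold 127, positions 150001 to 151000, with 61.6% in the female and 29.5% in the male (difference 32.1 ± 6.27 points, SE over 6 CpGs, chi-square adjusted p = 0.000109). All 6 CpGs were higher in the female, with 205 and 131 reads, and the N. vitripennis male was at 31.3% over its own CpGs. Scaffold 16 (2635001 to 2636000) had 55.7% against 32.2% (23.5 ± 8.31 points over 8 CpGs, chi-square adjusted p = 3.29e-11). Scaffold 81 (369001 to 370000) had 23.1% against 0.714%, but only 3 of its 5 CpGs were higher in the female (22.4 ± 9.87 points, chi-square adjusted p = 0.00221). Scaffold 7 (2666001 to 2667000) had 70.0% against 52.4%, with 10 of 12 CpGs higher in the female and a chi-square adjusted p of 1.60e-10. The others were on scaffold 1021 (15001 to 16000, 48.9% against 27.5%, a difference of 21.4 points that was 32.8 points and called at a minimum of 20 reads, and 9.93 points and not called at 5), scaffold 21 (15001 to 16000, 61.2% against 44.9%), scaffold 26 (1455001 to 1456000, 41.3% against 25.5%) and scaffold 309 (52001 to 53000, 81.9% against 66.3%).

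Among the windows called lower in the female, the largest difference was on scaffold 724, positions 29001 to 30000, with 70.5% in the female and 92.3% in the male (-21.8 ± 6.07 points, SE over 5 CpGs, chi-square adjusted p = 0.00606). At a minimum of 5 reads the difference was -7.96 points and was not called, and it was not called with the deeper library thinned. The N. vitripennis male had 0.571% there, over 5 CpGs of its own. Scaffold 357 (33001 to 34000) had 17.1% against 38.9% (-21.7 ± 7.85 points over 10 CpGs, chi-square adjusted p = 0.000617), where N. vitripennis was at 85.0% over 17 CpGs of its own. The difference was -5.75 points at a minimum of 20 reads and -3.06 points with the deeper library thinned, and it was called in neither case nor by Fisher's exact test on summed reads. Scaffold 7 (791001 to 792000) had 29.3% against 50.3%, with 9 of 11 CpGs lower in the female and a chi-square adjusted p of 2.77e-07, and -13.9 points, still called, with the deeper library thinned. Scaffold 19 (2793001 to 2794000) had 43.7% against 62.6%, with 13 of 16 CpGs lower and a chi-square adjusted p of 2.10e-09. Scaffold 1 (1410001 to 1411000) had 13.6% against 30.8%, with 10 of 10 CpGs lower and a chi-square adjusted p of 1.50e-07. The others were on scaffold 21 (2027001 to 2028000, 44.9% against 64.1%), scaffold 37 (468001 to 469000, 10.7% against 29.8%, with -7.09 points and no call at a minimum of 5 reads) and scaffold 5 (3323001 to 3324000, 67.4% against 85.8%).

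The counts rest on reads of 1 library per sex. With the test scaled by the dispersion of CpG differences (1.85), taken within windows at 30% or more on average over both libraries, 28 windows were called. Of the 16 windows named here, those on scaffolds 1, 7 (both windows), 16 and 19 were still called, and the other 11, with those on scaffolds 127 and 724 among them, were not. With the deeper library thinned, the windows on scaffolds 5, 21 (both windows), 26, 357 and 724 were not called, and those on scaffolds 37 and 127 had too few covered CpGs to be tested.

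**Figure D2:**
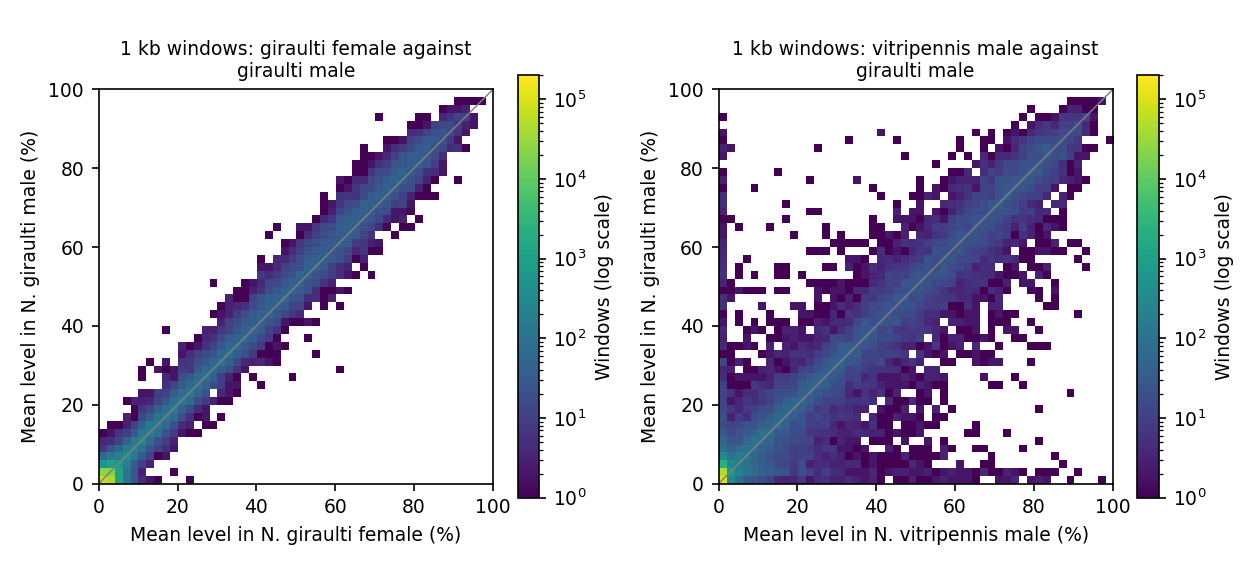
Mean methylation level of 1 kb windows in the N. giraulti male library (y axis, percent) against the N. giraulti female library (left, x axis, percent) and the N. vitripennis male library (right, x axis, percent), with colour for the number of windows on a log scale and a grey line at equal levels. Windows lie close to the line between the sexes (Pearson 0.993) and spread farther between the species (0.956), where some windows lie along both axes.

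At the level of single CpGs, 302 of 7400314 were called different between the N. giraulti sexes, of which 106 were higher and 196 lower in the female, and 76789 had an unadjusted p under 0.05. On scaffold 36, position 288171, 16 of 19 female reads and 0 of 18 male reads were methylated (84.2% against 0%, where 0 of 18 reads allows up to 16.7%, Fisher's exact test, adjusted p = 0.00542). On scaffold 24, the CpG at 433645 was at 95.6% in the female and 19.4% in the male (Fisher's exact test, adjusted p = 8.89e-07), and the CpG at 5284 at 93.0% and 19.05% (Fisher's exact test, adjusted p = 1.67e-12). The largest differences in the other direction were on scaffold 26 at 1368 (19.4% in the female and 93.8% in the male, Fisher's exact test, adjusted p = 0.0300), on scaffold 7 at 791837 (13.6% and 86.7%, Fisher's exact test, adjusted p = 0.0196) and on scaffold 127 at 275722 (15.4% and 88.1%, Fisher's exact test, adjusted p = 1.87e-09). Of the 302 CpGs, 25 lay in called windows. When only CpGs with a pooled level of at least 10% were tested, 2410 of 136206 were called, 968 of them higher in the female.

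Between the males of both species, most methylated windows were shared as well, and 2434 windows differed in level. Of 167992 windows with CpGs listed in both tables, 8779 were methylated in both libraries, where 552 would be if the libraries were independent. A further 873 were methylated in N. vitripennis alone and 837 in N. giraulti alone, so that 91.0% of the windows methylated in N. vitripennis were also methylated in N. giraulti and 91.3% the other way round. Windows that were on in 1 species and off in the other were few. Of 3852 windows at 50% or more in N. vitripennis, 69 (1.79%) were under 5% in N. giraulti, and of 3705 at 50% or more in N. giraulti, 62 (1.67%) were under 5% in N. vitripennis.

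The called windows made up 1.45% of those tested, and 1449 were higher and 985 lower in N. vitripennis. They were 23.2% of the 10489 windows methylated in either species. The corresponding share between the N. giraulti sexes was 1.42%, and the difference between these shares was not tested. These shares rest on unlike cutoffs. Without a minimum difference most species windows passed the adjusted p, and few windows of the sexes did. The adjustment therefore set a looser cutoff of the unadjusted p for the species. Differences of at least 25 points in either direction were seen in 368 windows higher and 198 lower in N. vitripennis. Of the called windows, 28.96% had a called window of the same direction directly beside them. In 100 random draws of methylated windows the mean was 12.5% and the highest value 15.98%. A single stretch that crosses a window border can call both windows, which the draws do not keep, so separate changes in neighbouring windows are not shown. Across windows, which are not independent replicates, Pearson's correlation was 0.956 over all windows and 0.865 over those methylated in either species, and Spearman's was 0.267 and 0.844.

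The largest differences were nearly complete over the CpGs compared. On scaffold 92, positions 430001 to 431000, the N. vitripennis male was at 97.5% and the N. giraulti male at 0% over 5 CpGs (97.5 ± 1.54 points, SE over CpGs, chi-square adjusted p = 8.67e-36), with 0 methylated of 104 N. giraulti male reads, which allows a level of up to 2.88%. These 5 CpGs lay at 430523 to 430689, so the same read can be counted at several of them, and the limit is then too low. The other CpGs of this window covered in the N. vitripennis male, which were not compared, were at 55.8%, 34.8%, 60% and 25.7%. A window 3 kb away on the same scaffold (427001 to 428000) had 89.9% against 1.06% (88.9 ± 1.61 points over 7 CpGs, chi-square adjusted p = 1.31e-97). Scaffold 95 (46001 to 47000) had 91.1% against 2.25% over 8 CpGs. The N. giraulti female was at 15.8% there over 14 CpGs of its own, which is not a comparison with the male at the same CpGs. The others higher in N. vitripennis were on scaffold 318 (10001 to 11000, 87.9% against 4.90%), scaffold 308 (293001 to 294000, 82.8% against 0.970%), scaffold 84 (699001 to 700000, 83.5% against 2.17%), scaffold 128 (19001 to 20000, 85.1% against 3.92%) and scaffold 384 (24001 to 25000, 82.9% against 1.74%).

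In the other direction, scaffold 5280 (1001 to 2000) was at 0% in the N. vitripennis male and 93.1% in the N. giraulti male (-93.1 ± 1.90 points over 9 CpGs, chi-square adjusted p = 5.01e-145), where 0 of 367 N. vitripennis reads allows a level of up to 0.817%. Scaffold 3720 (2001 to 3000) had 0.207% against 89.4% (-89.2 ± 5.60 points over 7 CpGs, chi-square adjusted p = 3.95e-71), and scaffold 349 (3001 to 4000) had 0.517% against 88.9% (-88.4 ± 2.61 points over 10 CpGs, chi-square adjusted p = 4.51e-126). N. vitripennis was at 0% on scaffold 2787 (1001 to 2000), scaffold 37 (304001 to 305000), scaffold 47 (1358001 to 1359000) and scaffold 34 (904001 to 905000), where the N. giraulti male was at 87.7%, 85.0%, 84.7% and 83.2%. The N. vitripennis reads there allow levels of up to 1.79%, 1.67%, 1.52% and 0.938%, if the counts at different CpGs are taken as separate reads. Scaffold 437 (153001 to 154000) had 1.202% against 85.7%. In all 16 windows named for the species every CpG compared differed in the direction of the window. This follows largely from their choice as the largest differences, which leave little room for a CpG to go the other way.

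**Figure D3:**
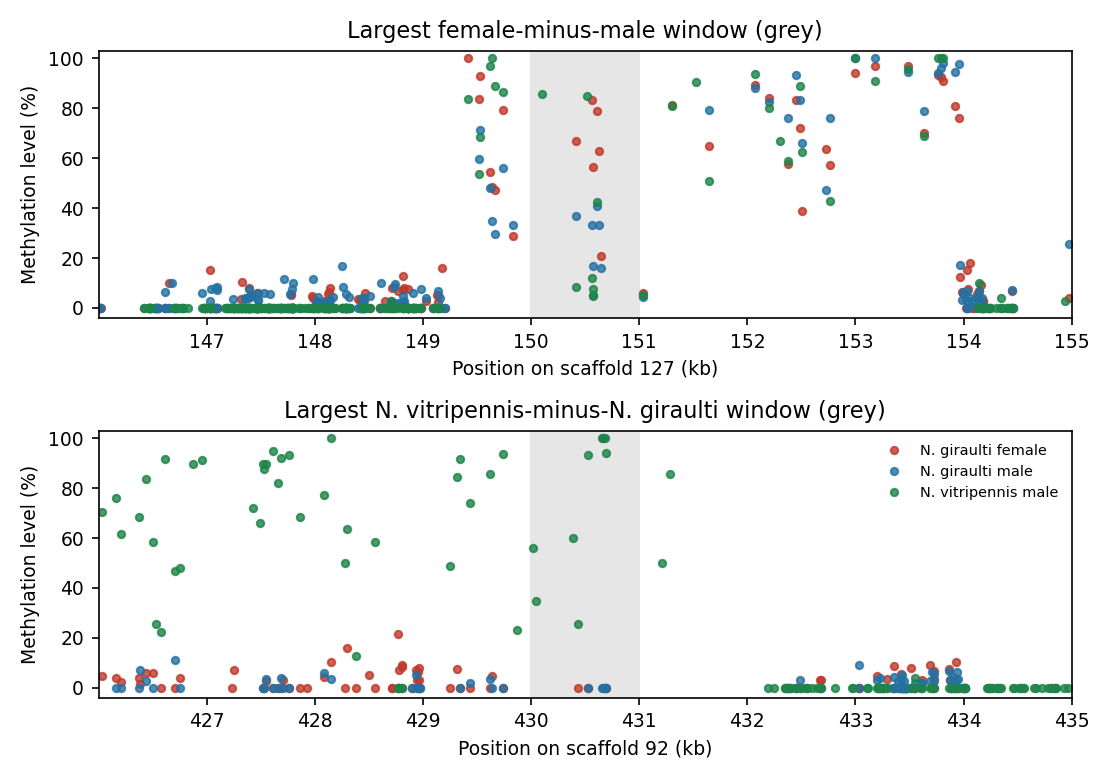
Methylation level of single CpGs with at least 10 reads (y axis, percent) by position in kb (x axis) around the window with the largest female-minus-male difference (top, scaffold 127) and the largest N. vitripennis-minus-N. giraulti difference (bottom, scaffold 92), with the window in grey and points in red for the N. giraulti female, blue for the N. giraulti male and green for the N. vitripennis male. The scaffold 127 window was not called with the dispersion scaling, and neither window could be tested at a minimum of 20 reads or with the deeper library thinned. The window means over the CpGs covered in both libraries compared are 61.6% and 29.5% for female and male at the top, and 97.5% and 0% for N. vitripennis and N. giraulti males at the bottom.

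The N. giraulti female library had the same direction against the N. vitripennis male at 2419 of the 2429 called windows (99.6%) with at least 5 CpGs covered in all 3 libraries. Both differences use the same N. vitripennis library, and draws in which every CpG had 1 level in all 3 libraries gave 69.2% on average and at most 71.2% in 100 draws. The draws held no difference, while the called windows were picked for a large one, so the draws are no baseline for the 99.6%. Part of the agreement can come from that shared library, which cannot be split. The tables do not show bases that differ between the species, which can pass for a methylation difference at a single CpG, and with the test scaled by the dispersion of CpG differences (4.47) 1131 windows were called. Without a minimum difference 117224 windows were called, 113918 of them lower in N. vitripennis, where windows under 5% in both libraries had median levels of 0.0858% in N. vitripennis and 1.73% in N. giraulti. This count can also depend on the genome used for the N. giraulti reads.

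Between covered CpGs, those that carried methylation in 1 species were more often missing from the list of the other. This was measured for CpGs of the male libraries that lay between CpGs listed and covered by at least 10 reads in the other species, at most 50 bp away on either side. Of N. vitripennis CpGs at 50% or more, 12.04% were missing from the N. giraulti list, against 7.16% of CpGs under 10% (ratio 1.68, 95% interval over scaffolds 1.61–1.75). Of N. giraulti CpGs at 50% or more, 9.78% were missing from the N. vitripennis list, against 6.03% of CpGs under 10% (ratio 1.62, 1.553–1.701). Over all covered CpGs, without this restriction, N. vitripennis went the other way, with 0.772% of the CpGs listed in it alone at 50% or more against 1.325% of those listed in both species, while N. giraulti had 1.579% against 0.860%. These tallies were chosen after seeing the data, and the rule by which the authors listed a CpG is not given in the sources used here.

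**Figure D4:**
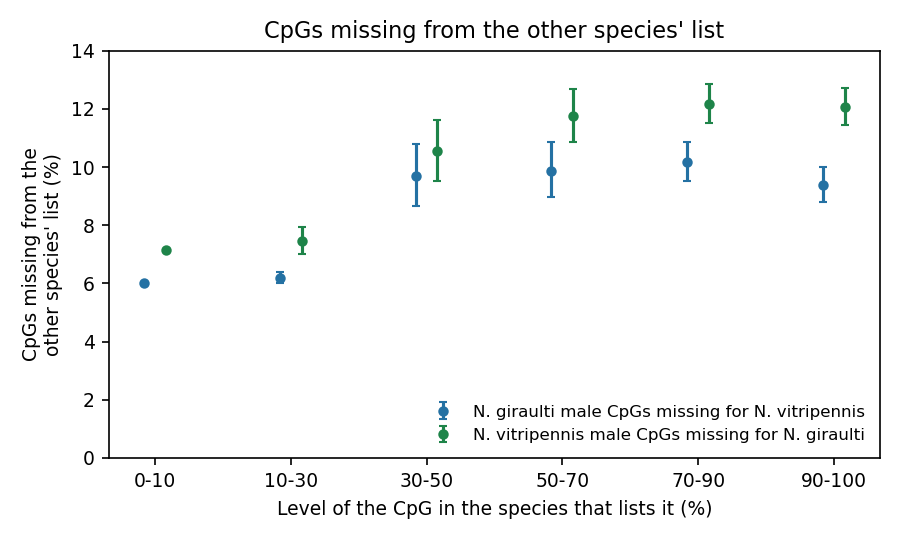
Share of CpGs between covered CpGs of the other species that are missing from the other species' list (y axis, percent) by the level of the CpG in the species that lists it (x axis, percent), with 95% exact binomial intervals as bars, for N. giraulti male CpGs (blue) and N. vitripennis male CpGs (green). The share is 6.03% and 7.16% for CpGs under 10% and lies at 9.39% and 12.1% for CpGs at 90% or more.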

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

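The dispersion scaling, the centring, the background subtraction, the equal weights, the CpGs covered in all 3 libraries and the thinning to 10 reads were chosen only after the result was seen. No named window changed direction under any alternative run. Under another test, another minimum difference or a minimum of 10 CpGs the difference of a window stays the same by construction. With no minimum difference every named window also stays called by construction. Most called windows were lower in the female, by a small margin with centring (51 higher, 54 lower), which balances the windows by construction, except with no minimum difference (1241 higher, 753 lower) and at 25 points (1 higher, 0 lower). Most were higher in N. vitripennis than in N. giraulti, except with no minimum difference (3306 higher, 113918 lower). The median difference over methylated windows between the sexes lay between -0.955 and -0.840 points. No paired analysis was possible because each group has 1 library. The comparison of machines, the strand sums, leaving out either N. vitripennis male sample, the gene lists and the genomic features were not run, since the columns used do not separate machines or strands and no annotation of that build was used here.

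Values are given for the N. giraulti female, N. giraulti male and N. vitripennis male in this order. The overall level was 3.28%, 2.68% and 1.64% at a minimum of 10 reads, 3.56%, 2.72% and 2.06% at 20 reads, 3.12%, 2.66% and 1.36% without the deepest CpGs, 2.79%, 2.55% and 1.24% as a mean of CpG levels, and 3.61%, 3.05% and 2.003% at CpGs covered in all 3 libraries. At 5 reads it was 3.23% in the first and 1.48% in the last. The order of the libraries held in each of these. With the background subtracted it was 1.25%, 0.915% and 1.15%, which put the N. vitripennis male above the N. giraulti male. Split by each library's own reads per CpG, the level was 1.83%, 2.13% and 0.365% at 1 to 9 reads and 1.98%, 2.18% and 0.777% at 10 to 19. There the N. giraulti female was below the male. At 40 to 59 reads the level was 4.88%, 2.81% and 2.50%.

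The share of methylated CpGs was 5.68%, 3.499% and 1.61% at 5 reads and 4.41%, 2.36% and 2.51% at 20 reads. It was 4.996% and 1.697% in the female and the N. vitripennis male without the deepest CpGs. A level of 20% gave 1.59%, 1.204% and 1.44%, a level of 50% gave 1.01%, 0.902% and 1.16%, and a binomial test against 1% gave 2.92%, 1.94% and 1.54%. With the background subtracted it was 3.33%, 2.09% and 1.62%, and at CpGs covered in all 3 libraries 4.91%, 3.15% and 2.14%. Thinned to 10 reads it was 17.3%, 16.5% and 3.29%, since a single methylated read then passes 10%. Among methylated CpGs whose next covered CpG lay within 50 bp, the share followed by another was 22.0%, 30.5% and 74.8%. At a level of 50% and within 100 bp it was 78.6%, 79.9% and 78.1%.

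Between the sexes, 1994 windows were called with no minimum difference, 1 at 25 points, 400 at 500 bp, 96 with at least 10 CpGs per window, 28 with the dispersion scaling and 0 with the sign-flip test. A sign-flip p of a window with few CpGs cannot pass the adjustment over 175872 windows, so this 0 says nothing about stability. The other alternatives called 105 to 160 windows. Pearson's correlation was 0.992 at 5 reads, 0.994 at 20 reads and 0.993 without the deepest CpGs. Of single CpGs, 2410 were called among those at a pooled level of 10%, and 224 to 370 otherwise. The named windows of the sexes were still called in 104 cases and lost in 53, most often under the sign-flip test (16), the 25-point minimum (15), the dispersion scaling (11) and the thinning (6). In 19 more cases a window had too few covered CpGs to be tested, as that on scaffold 127 at 20 reads, at 10 CpGs per window and with the thinning, and no named window was tested at 500 bp.

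Between the species, 117224 windows were called with no minimum difference, 566 at 25 points, 1325 with the sign-flip test, 3842 at 500 bp, 1580 with at least 10 CpGs per window and 1131 with the dispersion scaling. The other alternatives called 2129 to 2432 windows, and the named windows were still called in 153 cases and lost in 2, both under the sign-flip test and both with 5 CpGs, too few for that test to pass at any difference. In 21 more cases a window was not tested, as that on scaffold 92 (430001 to 431000) at 20 reads, at 10 CpGs per window and with the thinning. Apart from the counts set by construction, such as the minimum difference, the window size or the number of CpGs, the cause was not tested. Simulated shifts of 24.8 points at a single CpG were recovered in 1.26% of cases at these depths and with 7400314 tests. How much of this limit comes from depth and how much from the number of tests was not separated, and with 136206 tests 2410 CpGs were called in place of 302.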

Other observations

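The tests on strongly methylated CpGs, on read weights, on the background gap in the read-weighted level, on a CpG's own level and on reads thinned to 10 were chosen only after the result was seen, and the tallies in the next paragraphs were not planned.

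Runs of strongly methylated CpGs were of similar length in all 3 libraries. A run ended at any gap over 200 bp between covered CpGs and at any CpG under 50%. The spans therefore depend on this rule and do not give the length of methylated stretches. Runs of at least 5 CpGs at 50% or more, with gaps of at most 200 bp, numbered 5178 in the N. giraulti female, 5171 in the N. giraulti male and 5698 in the N. vitripennis male, with median spans of 347, 348 and 342 bp. They held 59.4%, 60.7% and 58.5% of all CpGs at that level. In both N. giraulti libraries the run with the most CpGs was on scaffold 7, with 39 CpGs at 927682 to 928583 in the female and 44 CpGs at 927520 to 928583 in the male. In the N. vitripennis male it was on scaffold 1 at 2229368 to 2230816, with 35 CpGs. Methylated windows held few CpGs, with a median of 18 listed CpGs against 57 in windows under 5% in the N. giraulti male, and 20 against 70 in the N. vitripennis male.

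Scaffolds differed widely in how much of them was methylated, and the same scaffolds were high and low in both species. On the 111 scaffolds with at least 200 windows, the share of methylated windows ran from 0% to 13.98% in the N. vitripennis male (median 5.17%) and from 0% to 14.2% in the N. giraulti male (median 5.26%). Across scaffolds, which are not independent replicates, Pearson's correlation of the shares was 0.988. Scaffold 179 had no methylated window among 425 in either species, and scaffolds 80 (337 windows), 119 (311) and 174 (246) had none either. Scaffold 16 had 10.05% of 3544 windows methylated in both species, against 5.09% and 5.32% of 3476 windows on scaffold 18 in N. vitripennis and N. giraulti. These scaffolds were chosen after their values were seen.

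More CpGs reached 10% in the N. giraulti female library (5.03%) than in the male (2.95%), while the overall level differed by 0.518 points at the same CpGs. A higher share of strongly methylated CpGs in the female is argued against, since at the same CpGs the gap at 50% or more was -0.9772% of the gap at 10% or more. Whether the surplus sits in windows with little methylation was not decided, since windows under 5% in the N. vitripennis male held 99.17% of it but also 96.8% of the CpGs, and although the gap per CpG was larger there (3.69% against 1.502%, and 41.3% against 40.8% elsewhere), many CpGs elsewhere already stood above 10%. A uniform background at each library's depth gave 59.62% of the gap, and with every CpG thinned to 10 reads, where a single methylated read passes 10%, the shares were 17.3% and 16.5%, so that the background cannot be told apart from weak methylation or from an uneven background. The sex of the wasps stays open as an untested explanation.

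The higher read-weighted level of the N. giraulti female may come from where its reads fall. With the female levels weighted by the male depths at the same CpGs, 20% of the gap was left (0.104 of 0.518 points), and female depth fell with the number of CpGs in a window (Spearman -0.414, against 0.0810 in the male, across windows). A higher background in the female equals 43.31% of the gap (0.224 points), and it cannot be told apart from a real difference because background and weak methylation are read alike. This background gap is itself weighted by each library's own depth and was taken over unlike sets of CpGs. It therefore overlaps with the effect of the read weights, and these shares cannot be added. Sex stays open as an untested explanation of the 0.104 points left with the male weights, of which background can be a part.

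Between covered CpGs, those methylated in 1 species were more often missing from the other's list, and too few reads are argued against, since with flanking CpGs at 30 or more reads the ratio was 1.609 in the lower direction (95% interval 1.47–1.76) and 1.72 in the other. A lower number of CpGs around methylated CpGs could account for part of it, since the ratio fell to 1.26 (1.203–1.318) and 1.40 (1.33–1.45) in strata of local CpG number, and whether it accounts for the rest cannot be told apart with these strata. Whether a CpG's own level plays a role within methylated stretches was not decided. Between flanking CpGs at 50% or more in the other species, CpGs at 80% or more were missing less often than those at 10 to 50%. The ratio was 0.7963 (0.706–0.9004) in the lower direction and 0.813 (0.724–0.926) in the other. CpGs under 10% were left out, and the tables do not show bases that differ, which can pass for a low level. Loss of methylated cytosines by deamination in the species that lacks the CpG is a hypothesis that was not tested, since the tables do not give the base that replaced the CpG.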
